A study of Salamandra salamandra with 40 samples.

How the data were processed

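RNA from tail-tip tissue of fire salamanders (Salamandra salamandra) was measured on 40 one-colour Agilent arrays, 4 from each of 10 field sites in Germany. The deposited scanner files hold linear intensity values of 62976 spots per array, read with Agilent Feature Extraction 10.7.3.1 under its one-colour protocol, per the file headers. The processed intensity used here was background-subtracted and detrended within each array by that software, per the file headers, and was not scaled between arrays. How the RNA was labelled and the arrays designed is not given in the sources used here. The deposited value table of the authors holds a second set of linear intensity values for 11797 contigs, all matched by contig name. Its columns had 75th percentiles of 1.01 to 1.03 and medians of 0.230 to 0.288. Its log2 values correlated with the scanner values across contigs at 0.913 to 0.995, so it ran in the same direction, and how its background was treated stays unknown.

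The array carries 12757 probes of 60 nucleotides for 12744 assembled contigs, each probe in 4, 5 or 10 spots. The files pair no probe with a gene name, and no reference for this species was used, so contigs appear under the identifiers of the array design, with no gene, chromosome or genome position. For 10558 probes the contig name gives the start and end of a stretch within the contig. The length of every such stretch is a multiple of 3, so it is called a coding stretch. The lists of genes chosen beforehand, which held markers of skin, muscle, blood, pigment and immune cells among others, could therefore not be applied, and none of their tests was run.

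Control spots were left out, and spots flagged as outliers by the scanner software were set to missing. Each array's processed signal was divided by its own 75th percentile over all spots but controls, flagged ones included. It was put on the log2 scale, and the unflagged spots of one probe were averaged. A probe counted as well above background on an array when most of its spots carried that flag. The 11968 probes that were so on at least 4 arrays were tested, and 789 were left out. Where a probe was not well above background on any array of a group, the difference is given as a lower bound. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

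Tests were made with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with Benjamini-Hochberg adjustment and a threshold of 0.05. Scanner files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. A moderated F-test compared all 10 sites, and a second compared the 8 sites whose sample titles begin with Ko. Moderated contrasts in the fit of 40 arrays compared both sites of each slide. On the means of each site's 4 arrays, 5 sites with names ending in -bach were compared with 3 sites given only as a code, and Wolfsburg and Reitlingstal were compared with the 8 Ko sites. The German ending means brook, but the labels state no habitat, and these groups are called brook-named and code-only. The labels do not state that samples are separate animals, although the title numbers name specimens, so p-values measure only the spread between these samples, or between site means.

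Groups, designs, the naming rule and the alternatives other than those named last were set before the data were examined. The rule named, by identifier, at most 2 contigs with the largest difference each way per comparison and at most 2 with the largest range of site means per F-test. For KoE and KoV2, where no probe passed, it gave the contigs of smallest p each way as values. Alternatives covered the background correction (normexp with an offset of 50), quantile and median scaling, the filter on dim probes, outlier spots, the values of the authors, blocks for slide, array column and title number, the unit of replication, and leaving out each array or site. Leaving out 3 arrays of low signal, array quality weights and slide as a fixed block were chosen after seeing the data.

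The 75th percentile of processed signal ranged from 124 to 710 between arrays, and 72.9% to 92.9% of spots were well above background. No spot was saturated. The number of arrays limits the precision. The tests were tested on simulated data of 11968 probes with 200 changed ones. At a log2 difference of 1, the within-slide test recovered 60% of changed probes, the F-test over 10 sites 57%, the brook-named comparison 75% and the comparison of Wolfsburg and Reitlingstal with Ko 58%. At a log2 difference of 2 these shares were 94%, 90%, 95% and 89%. The simulated values were drawn independently from normal distributions around each probe's mean, with the spread of the real data and no shared slide effect. These shares therefore do not describe recovery where sites share a slide effect or single arrays stand far apart.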

Results

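Gene expression was measured in tail tips of fire salamanders, a European amphibian, sampled at 10 German field sites with 4 samples each. The sites were Wolfsburg and Reitlingstal, the brook-named Vennerbach, Klufterbach, Hittelbach, Annabergerbach and Katzenlochbach, and the code-only KoE, KoV2 and KoIc. Each of 5 slides held 8 arrays from 2 sites and was scanned apart from the others, and each site filled 1 row of its slide. The pairs were Wolfsburg with Reitlingstal, Vennerbach with Klufterbach, Hittelbach with Annabergerbach, KoE with KoV2, and KoIc with Katzenlochbach. A comparison of both sites of a slide was therefore also one of its rows. The mean 75th percentile of signal was 311 ± 81.1 (SD, n = 4) at Wolfsburg and 194 ± 79.0 (SD, n = 4) at Reitlingstal. It lay between 486 and 632 at the 8 Ko sites. Wolfsburg 2, Reitlingstal 1 and Reitlingstal 6 had the lowest values, at 196, 136 and 124.

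**Figure D1:**
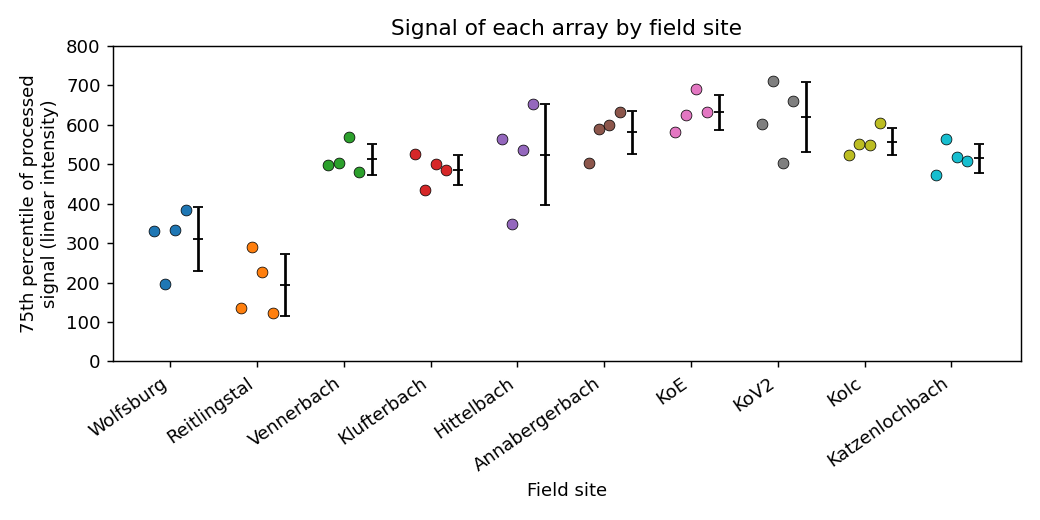
The 75th percentile of processed signal (linear intensity) of each array is plotted by field site, with the mean and SD of 4 arrays beside the points. The arrays of Wolfsburg and Reitlingstal lie between 124 and 385, and those of the other sites between 348 and 710.

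The comparison of all sites asked which transcripts differed between field sites. Contig comp320802_c0_seq1 had the widest range of site means, from 5.51 ± 3.53 (SD, n = 4) at Reitlingstal to -7.55 ± 0.08 at Vennerbach, on the log2 scale relative to each array's 75th percentile. It was not well above background on any Vennerbach array, which made the difference at least 2298-fold (limma F-test, adjusted p = 4.43e-07), and at least 1260-fold, 7020-fold and 1240-fold without Reitlingstal 1, 3 and 6. Contig comp396174_c0_seq2, with a coding stretch from 165 to 1769, averaged 2.18 ± 0.87 (SD, n = 4) at Wolfsburg and -7.32 ± 0.53 at Annabergerbach. It was not well above background at Annabergerbach, and the difference was at least 202-fold (limma, adjusted p = 1.28e-04). In all, 9593 of 11968 probes differed between the 10 sites, 7013 of them with a range of at least 2-fold and 491 with a range of at least 8-fold. This count holds site and slide together. With slide as a fixed block, chosen after seeing the data, the differences within slides were called for 2094 probes.

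Among the 8 Ko sites, comp370813_c0_seq1 (coding stretch from 2 to 871) was highest at Hittelbach, with -0.62 ± 1.14 (SD, n = 4), and lowest at KoIc, with -6.79 ± 0.26. It was not well above background on any KoIc array and differed by at least 28.9-fold (limma F-test, adjusted p = 0.00187). Contig comp90855_c0_seq1 was also highest at Hittelbach, with 0.78 ± 1.18 (SD, n = 4), and was lowest at KoE, with -5.07 ± 0.56 and 3 of 4 arrays well above background (limma, adjusted p = 9.35e-05). In all, 5386 of 11968 probes differed between these sites, 2201 of them by at least 2-fold and 76 by at least 8-fold. The count was 596 with slide as a fixed block, chosen after seeing the data, and 3521 when only probes well above background on every array were kept.

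Resemblance between arrays was compared within sites, within slides and between slides. The median correlation between arrays, across probes, which are not independent replicates, was 0.972 within a site, 0.969 between both sites of a slide and 0.952 between slides. Among the Ko sites it was 0.974, 0.972 and 0.963. Ko arrays correlated with those of Wolfsburg and Reitlingstal at a median of 0.913. The median share of a probe's variance that lay between sites was 48.6% over 10 sites and 28.7% over the Ko sites. Each site lay on 1 slide, so this share holds site and slide together.

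**Figure D2:**
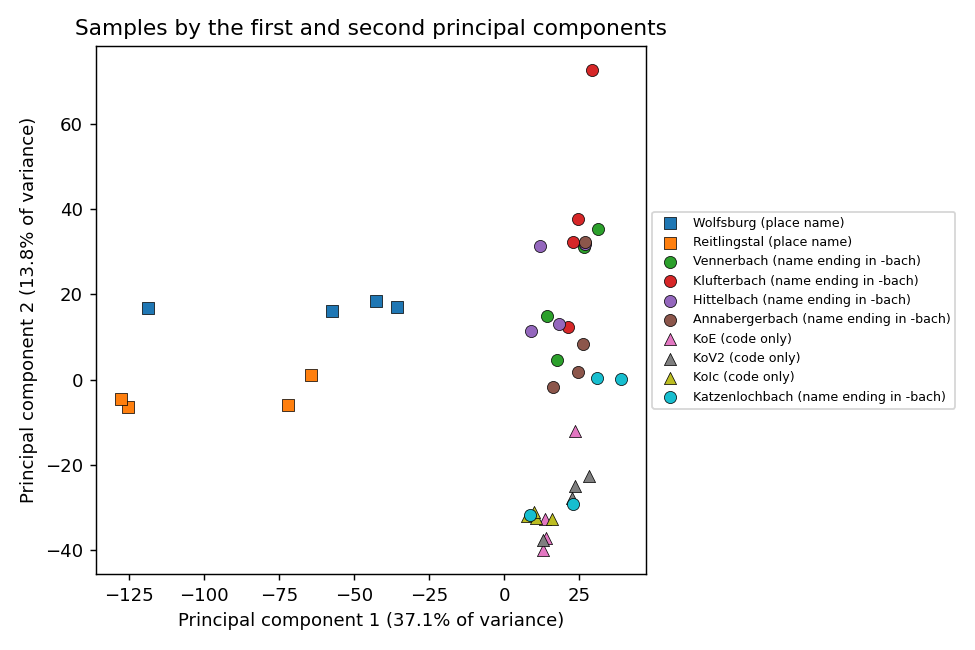
Each sample is placed by its scores on the first principal component (x axis, 37.1% of variance) and the second (y axis, 13.8% of variance), in arbitrary units, with colours for sites and marker shapes for the kind of site name. Wolfsburg and Reitlingstal samples lie at negative values of the first component, from -127.7 to -35.8, and code-only samples lie between -40.0 and -12.1 on the second.

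Wolfsburg and Reitlingstal were compared with the 8 Ko sites because the sample titles set these apart. Contig comp320802_c0_seq1 averaged 4.18 ± 1.88 (SD of site means, n = 2) at Wolfsburg and Reitlingstal and -6.11 ± 1.43 (n = 8) at the Ko sites. The log2 difference was 10.29 ± 1.00 (SE; limma, adjusted p = 2.91e-05), and the contig was well above background on 8 of 8 and 7 of 32 arrays, so the Ko mean rests mostly on values near background. Contig comp413570_c0_seq3 (coding stretch from 534 to 1628) was higher by 8.37 ± 0.42 (SE; adjusted p = 6.84e-07) and was well above background on 8 of 8 and 16 of 32 arrays. In the other direction, comp418912_c0_seq1 (113 to 1252) differed by -6.47 ± 0.82 (SE; adjusted p = 1.41e-04) and comp29797_c0_seq1 (371 to 1402) by -5.93 ± 0.75 (SE; adjusted p = 1.32e-04). They were well above background on 1 of 8 and 5 of 8 arrays of Wolfsburg and Reitlingstal and each on 31 of 32 Ko arrays, so the first difference is set mostly against values near background. With 1 array left out, the difference was 11.23 and 11.09 for comp320802_c0_seq1 (without Wolfsburg 5 and Reitlingstal 3), -7.24 for comp418912_c0_seq1 (without Reitlingstal 1) and -6.53 and -6.80 for comp29797_c0_seq1 (without Wolfsburg 5 and Reitlingstal 2). Contigs comp320802_c0_seq1 and comp413570_c0_seq3, and comp90855_c0_seq1 named above, belonged to a set of 26 contigs whose mean was highest on Wolfsburg 2, Reitlingstal 1 and Reitlingstal 6.

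The difference involved 5368 probes, 2715 higher and 2653 lower at Wolfsburg and Reitlingstal, of which 2486 differed by at least 2-fold and 92 by at least 8-fold. Of the called probes, 62 were well above background on every Ko array and on no array of Wolfsburg or Reitlingstal, and 2 showed the opposite. The share of spots well above background averaged 82.1% at Wolfsburg and 77.3% at Reitlingstal, against 85.5% to 92.0% at the Ko sites. The 62 and 2 may therefore partly reflect array signal, which was not tested. Wolfsburg and Reitlingstal shared a slide that held no Ko sample, so area and slide could not be told apart. Without Reitlingstal, 2994 probes were called. The direction of calls depended on background correction and scaling: 6221 were higher and 1732 lower after normexp correction with the same scaling, which moved the median of all probes from 0.00558 to 0.408. After quantile scaling 2656 were higher and 3025 lower, with a median of -0.0475, and 2296 were higher and 3178 lower after median scaling, with a median of -0.120.

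Within slide 1, comp26108_c0_seq1 (coding stretch from 66 to 602) was higher at Wolfsburg, with 1.91 ± 1.55 (SD, n = 4), than at Reitlingstal, with -6.06 ± 0.56. It was not well above background on any Reitlingstal array, and the difference was at least 79.7-fold (limma, adjusted p = 9.27e-08), and at least 136-fold without Wolfsburg 2. Contig comp389861_c0_seq3 (336 to 1391) was at least 14.3-fold higher at Wolfsburg (adjusted p = 0.0114; at least 33.6-fold without Wolfsburg 1), a call that ended after normexp correction. Lower at Wolfsburg were comp1005157_c0_seq1 (3 to 308), by at least 9.96-fold (adjusted p = 9.22e-05), and comp104452_c0_seq1 (196 to 1575), with a log2 difference of -3.60 ± 1.08 (SE; adjusted p = 0.0119). The latter was well above background on 1 of 4 Wolfsburg arrays, Wolfsburg 2, at -1.13 against a site mean of -5.56 ± 2.96 (SD, n = 4), so its difference rests on values near background and on that array. The difference of comp104452_c0_seq1 was -5.07 without Wolfsburg 2, and its call ended without Wolfsburg 1 (-3.07, adjusted p = 0.0604) and without Wolfsburg 5 (-3.10, adjusted p = 0.0546). In all, 3725 probes were called, 1169 higher and 2556 lower at Wolfsburg. Only 8 were called when the spread came from this slide's 8 arrays alone. The fits without the 3 arrays of lowest signal and with array quality weights, chosen after seeing the data, gave 2417 and 6468. The weights were 1.345 and 0.752 for the low-signal Reitlingstal 1 and 6, and 0.152 and 0.213 for Reitlingstal 2 and 3. The low-signal Wolfsburg 2 had 0.135. At Reitlingstal the weighted fit therefore rests mostly on the low-signal arrays. The split was 1601 to 1881 after quantile scaling, 2047 to 1742 after median scaling and 860 to 5076 after normexp correction. The count was 2146 without Wolfsburg 1, 2440 without Wolfsburg 5, 2220 without Reitlingstal 1 and 2328 without Reitlingstal 6.

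Contig comp26108_c0_seq1 was also called in 2 other slide pairs. At Vennerbach it averaged -6.23 ± 1.22 (SD, n = 4) and at Klufterbach -2.41 ± 0.94, a log2 difference of -3.82 ± 0.77 (SE; limma, adjusted p = 0.0146) that is set mostly against values near background, with 1 of 4 Vennerbach arrays well above it. This call of comp26108_c0_seq1 ended without Vennerbach 1, Vennerbach 6 and Klufterbach 2 (-3.41, -3.67 and -3.83, adjusted p = 0.0918, 0.0505 and 0.0560). It was at least 6.04-fold higher at Hittelbach, with -2.88 ± 1.11 (SD, n = 4), than at Annabergerbach, with -7.14 ± 0.30 (adjusted p = 0.00306). The calls of these last 2 pairs ended after normexp correction and with the authors' table. Its probe sequence was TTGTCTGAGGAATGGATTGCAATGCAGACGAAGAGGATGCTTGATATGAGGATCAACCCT.

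**Figure D3:**
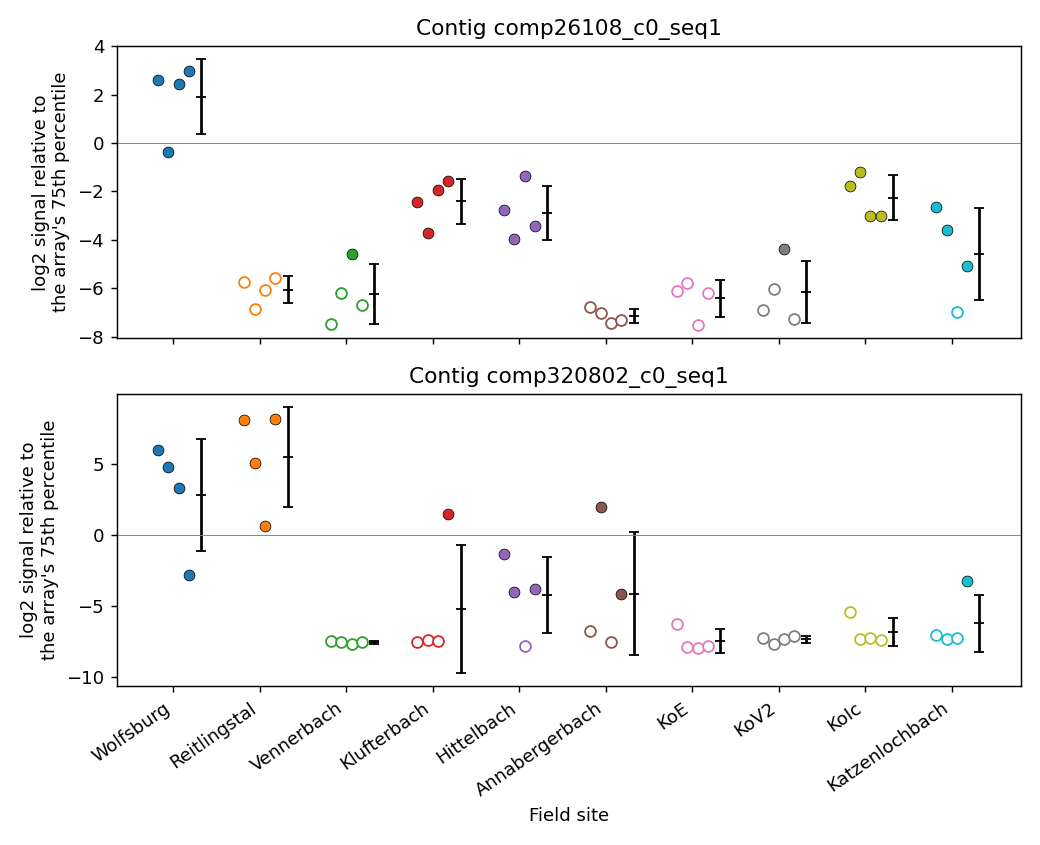
The log2 signal relative to each array's 75th percentile (y axis) is plotted per sample for 2 contigs by field site (x axis), with the mean and SD of 4 samples beside the points. Filled points were well above background and open points were not. For comp26108_c0_seq1 the 4 Wolfsburg samples lie between -0.39 and 2.99 and the 4 Reitlingstal samples between -6.84 and -5.59, and comp320802_c0_seq1 reaches 8.17 at Reitlingstal.

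Between Vennerbach and Klufterbach, comp408757_c1_seq4 (coding stretch from 1536 to 2006) was higher at Vennerbach by 2.20 ± 0.44 (SE; limma, adjusted p = 0.0146), set mostly against values near background, with 1 of 4 Klufterbach arrays well above it. Contig comp122934_c6_seq2 was higher by at least 1.12-fold (adjusted p = 0.0241), with 1 of 4 Vennerbach arrays and 0 of 4 Klufterbach arrays well above background. Contig comp848053_c0_seq1, well above background on 0 of 4 Vennerbach and 3 of 4 Klufterbach arrays, was at least 4.08-fold lower at Vennerbach (adjusted p = 0.0426). The calls of these 3 contigs ended after normexp correction. That of comp408757_c1_seq4 also ended without Vennerbach 1, 4 or 6 or Klufterbach 2 or 3 (1.89 to 2.12, adjusted p = 0.0505 to 0.103), and its difference was 2.86 without Klufterbach 6. That of comp122934_c6_seq2 ended without Vennerbach 3, 4 or 6 or Klufterbach 2, 3 or 6 (adjusted p = 0.0505 to 0.180), and it had no fold without Vennerbach 4. That of comp848053_c0_seq1 ended without any 1 Vennerbach array, Klufterbach 2 or 3 (adjusted p = 0.0855 to 0.320) and without any 1 of 15 arrays of other slides, and it was at least 2.45-fold lower without Klufterbach 3 and 8.37-fold without Klufterbach 5. In all 44 probes were called, 7 higher and 37 lower at Vennerbach. The count was 11, 29, 16 and 28 without Vennerbach 1, 3, 4 and 6, 16 without Klufterbach 2 and 12 without Klufterbach 3. It was 14 with the title number as a replicate block, 2 with this slide's arrays alone and 18 with the authors' table. In fits chosen after seeing the data, it was 109 without the 3 arrays of lowest signal and 93 with array quality weights.

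Between Hittelbach and Annabergerbach, comp421199_c0_seq1 (2676 to 3401) was higher at Hittelbach by 3.46 ± 0.45 (SE; limma, adjusted p = 9.14e-05). Contigs comp422439_c0_seq1 (3068 to 4030) and comp412275_c0_seq2 (135 to 4106) were lower there, with differences of -2.23 ± 0.44 and -1.95 ± 0.41 (SE; adjusted p = 0.00606 and 0.0106). The difference of comp422439_c0_seq1 was -2.88 without Hittelbach 2, and its call ended without Hittelbach 4 (-1.93, adjusted p = 0.0525). In all 96 probes were called, 87 higher and 9 lower at Hittelbach. The count was 48 and 56 without Hittelbach 4 and 5, and 54, 59 and 56 without Annabergerbach 1, 4 and 6. It was 51 with this slide's arrays alone and also with the authors' table. In fits chosen after seeing the data, it was 284 without the 3 arrays of lowest signal and 323 with array quality weights.

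Between KoIc and Katzenlochbach, the only slide with both kinds of site name, comp357275_c0_seq1 was at least 14.0-fold higher at KoIc (limma, adjusted p = 0.0385). Contig comp409161_c0_seq2 (1 to 591) was higher there by 3.90 ± 0.94 (SE; adjusted p = 0.0415). It was well above background on 1 of 4 Katzenlochbach arrays, sample 2, at -3.03 against a site mean of -6.21 ± 2.12 (SD, n = 4), so its difference rests on values near background and on that array. Contig comp95105_c0_seq1 was at least 2.29-fold lower at KoIc (adjusted p = 1.17e-07; well above background on 0 of 4 KoIc and 3 of 4 Katzenlochbach arrays), a call that ended after normexp correction, and comp408714_c0_seq1 (94 to 1041) differed by -2.22 ± 0.49 (SE; adjusted p = 0.0252). The call of comp357275_c0_seq1 ended without any 1 KoIc array or Katzenlochbach 1 or 3 (adjusted p = 0.0634 to 0.137). That of comp409161_c0_seq2 ended without any 1 KoIc array or Katzenlochbach 1, 3 or 4 (3.50 to 4.16, adjusted p = 0.0727 to 0.177), and its difference was 4.96 without Katzenlochbach 2. That of comp408714_c0_seq1 ended without KoIc 2, 4 or 5 or Katzenlochbach 1 or 3 (-2.31 to -1.98, adjusted p = 0.0579 to 0.137). In all 89 probes were called, 52 higher and 37 lower at KoIc, against 42 and 60 after quantile scaling, 46 and 55 after median scaling and 49 and 83 after normexp correction. The count was 35, 17, 16 and 49 without KoIc 2, 4, 5 and 6, and 20, 137, 14 and 134 without Katzenlochbach 1, 2, 3 and 4. It was also 208 without Wolfsburg 2 and 152 without Hittelbach 6, which enter through the shared spread, and 15 with the title number as a replicate block. It was 258 with this slide's arrays alone and 34 with the authors' table and, in fits chosen after seeing the data, 408 without the 3 arrays of lowest signal and 1688 with array quality weights.

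No probe was called between KoE and KoV2 with limma. Of 11968 tested, 291 had an unadjusted p under 0.05, less than the share of 0.05 that chance alone gives. Contig comp133224_c0_seq1 averaged 0.11 ± 0.07 (SD, n = 4) at KoE and -0.37 ± 0.18 at KoV2, and comp421613_c2_seq21 averaged 2.38 ± 0.13 and 1.95 ± 0.18. Contig comp92835_c0_seq2 averaged -4.41 ± 3.52 (SD, n = 4; 2 of 4 arrays well above background) at KoE and -0.57 ± 0.56 at KoV2, and comp116173_c0_seq3 averaged 0.52 ± 0.26 and 1.64 ± 1.05. None of these 4 differences passed the threshold with all arrays. Contig comp92835_c0_seq2 passed it without KoE 1 (-4.93, adjusted p = 0.00135) and without KoE 5 (-4.78, adjusted p = 0.00671), and its difference was -2.79 and -2.86 without KoE 2 and 4. Contig comp116173_c0_seq3 passed it without KoV2 6 (-1.52, adjusted p = 0.0283).

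Brook-named and code-only sites within Ko were compared by site means. Contigs comp107326_c0_seq2 and comp388159_c0_seq5 were higher at brook-named sites by 1.19 ± 0.18 (SE; n = 5 and 3 site means; limma, adjusted p = 0.0486 for both). They carry probes of identical sequence and count as 1 measurement. Contig comp425111_c0_seq7 (coding stretch from 1 to 4413) was lower at brook-named sites, with a difference of -2.50 ± 0.35 (SE; adjusted p = 0.0412), and was well above background on 12 of 20 brook-named and 12 of 12 code-only arrays. Its arrays lay far apart at KoE, with -1.50 ± 2.83 (SD, n = 4), and at KoV2, with -1.40 ± 2.42. Contig comp285182_c0_seq1 (203 to 664) was not well above background on any of 20 brook-named arrays and was on 3 of 12 code-only arrays, at least 1.62-fold lower (adjusted p = 0.0412). Those 3 arrays, 1 of each code-only site, carry the fold, with KoV2 at -4.40 ± 4.70 (SD, n = 4) and its highest array at 2.62, and without KoV2 1 there was no fold. The calls of comp107326_c0_seq2, comp388159_c0_seq5, comp425111_c0_seq7 and comp285182_c0_seq1 ended without Vennerbach, Klufterbach, Hittelbach, Annabergerbach, KoE or KoV2 (adjusted p = 0.0540 to 0.183), and those of the first 2 also without KoIc (adjusted p = 0.0636 and 0.0622).

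In all 26 probes of 25 distinct sequences were called, 2 higher and 24 lower at brook-named sites, and 3068 had an unadjusted p under 0.05. The share of spots well above background averaged 85.5% to 88.7% at brook-named and 88.2% to 92.0% at code-only sites. The direction of the calls may therefore partly reflect array signal, which was not tested. None of the 26 was called between Katzenlochbach and KoIc, which share a slide, where the median difference in the direction of the call was 0.86, against 1.19 over the site means. Both sites also enter the calls, so this is no separate test. The count was 0 with slide as a random block, after normexp correction, after quantile scaling and among probes well above background on every array, 3 after median scaling, 8 with the authors' table and 516 with no filter on dim probes. It was 0 without Vennerbach, Klufterbach, Annabergerbach, KoE or KoV2, 1 without Hittelbach, 55 without KoIc and 1808 without Katzenlochbach.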

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

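The tests of Katzenlochbach, those on the second principal component among them, and of the contigs high on 3 arrays were chosen after the results were seen. A sample or site stood far from the others of its group in 15 of 84 groups examined, where chance gives about 1 in 20. Of the arrays, Wolfsburg 2 had 78.4% of spots well above background, against 83.0% to 83.5% on its site's others, and Klufterbach 3 had 83.1%, against 86.5% to 86.6%. Klufterbach 3 also had a score of 2.08 on the brook-named scale described for Katzenlochbach, against 1.01 to 1.08.

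On the log2 scale, Wolfsburg 2 stood apart for comp26108_c0_seq1, at -0.39, and for comp104452_c0_seq1, at -1.13, and Wolfsburg 1 for comp389861_c0_seq3, at -4.26. Vennerbach 3 lay at -4.77 for comp408757_c1_seq4, Hittelbach 2 at -1.29 for comp421199_c0_seq1 and at 1.00 for comp412275_c0_seq2, and Annabergerbach 6 at 2.76 for the latter. KoE 1 lay at 0.22 for comp133224_c0_seq1. For comp409161_c0_seq2, KoIc 4 lay at -3.10 and Katzenlochbach 2 at -3.03. Among site means, Katzenlochbach lay at -6.63 for comp285182_c0_seq1 and KoIc at -3.68 for comp413570_c0_seq3.

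The difference of Wolfsburg and Reitlingstal from the Ko sites was tested against 3 technical explanations. The 3 arrays of low signal do not account for it alone, since 4015 probes were called without them. Slide differences of the size seen elsewhere do not either: the sites of another slide against the other Ko sites gave at most 2 called probes, against 5368. Differences among the remaining slides enter the spread of that test, so its count does not show that Ko slides are alike. By arrays, pairs of Ko sites on different slides gave 54 to 2684 called probes. Wolfsburg or Reitlingstal against single Ko sites gave 4461 to 7530. Loss of hybridisation at single probes stays open. In 11 comparisons between different probes of the same assembled component, the partner showed a median of 60.4% of the first probe's difference. A pair of probes could enter in both orders. Slide 1 itself and the area cannot be told apart, because no Ko sample was on that slide.

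Katzenlochbach 2 and 4 lay among the code-only samples on the second principal component, at -29.1 and -31.7, while samples 1 and 3 lay at 0.33 and 0.21. A score came from the 100 probes that best parted the kinds of site on the other slides, with 0 at the midpoint and 1 at the brook-named mean. It put 16 of 20 brook-named and 8 of 12 code-only samples on their own side, and all 4 Katzenlochbach samples on the code-only side, from -0.79 to -0.35. For Katzenlochbach and KoIc, the code-only sites behind the score were KoE and KoV2, which share 1 slide without a brook-named site. For KoE and KoV2, only KoIc stood behind it. The score therefore could not tell the kind of site name from the slide. On the component a swap of labels with KoIc is argued against. There 0 KoIc samples, at -32.6 to -31.0, lay nearest to samples 1 or 3. The score could not test a swap, with 0 KoIc and 0 Katzenlochbach samples on the brook-named side. Low signal of samples 2 and 4 is argued against too, since sample 2 was brighter than samples 1 and 3. Samples 1 and 3 had fewer spots well above background, 82.9% and 84.1% against 87.1% and 88.0% on samples 2 and 4. Whether this difference in signal parts them on the component was not tested. The slide shared with KoIc stays open for the scores, where samples 2 and 4 lay only 0.963 within-site SDs below samples 1 and 3, but acting on all 4 samples it would not by itself part them on the component, where the nearest of them lay 3.55 such SDs apart. A property of the site itself was not tested.

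A set of 26 contigs, comp320802_c0_seq1, comp413570_c0_seq3 and comp90855_c0_seq1 among them, was high on Wolfsburg 2, Reitlingstal 1 and Reitlingstal 6, with means of 2.66 to 3.10 against -5.06 to -3.69 on Ko arrays. The other Wolfsburg and Reitlingstal arrays lay between, from -3.43 to 0.09. Scaling of dim arrays is argued against, since before scaling the lowest median of the 3 arrays was 19.3 times the highest on Ko arrays. Background is too, since negative controls on the 3 arrays were at most 1.11 times those of the slide's others. RNA from other material on these arrays stays open, and no biological explanation was tested, because the contigs have no gene names.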

How the results depend on the processing

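The fits without 3 arrays of low signal, with array quality weights and with slide as a fixed block were chosen after seeing the data. All values are called probes, and the cause of each change was not tested unless stated. The count over 10 sites lay between 6503 and 10941 in all other settings run and was 2094 with slide as a fixed block, which keeps only differences within slides. The Ko count was 596 with that block, 3521 among probes well above background on every array, where fewer probes were tested, and 2201 with a range of at least 2-fold. A log2 difference of at least 1 left 1118 probes for Wolfsburg and Reitlingstal, 28 for Vennerbach and Klufterbach, 59 for Hittelbach and Annabergerbach, 37 for KoIc and Katzenlochbach and 2486 for Wolfsburg and Reitlingstal against Ko. In the same order of slide pairs, the 8 arrays of the slide alone gave 8, 2, 51 and 258. Without the 3 arrays the pairs gave 2417, 109, 284 and 408, and array quality weights gave 6468, 93, 323 and 1688, with 1 for KoE and KoV2. The authors' table gave 18, 51 and 34 for the last 3 of these pairs and 1 for KoE and KoV2. Normexp correction gave 5936 for Wolfsburg and Reitlingstal.

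The brook-named count of 26 was the least stable. It was 0 after normexp correction, quantile scaling, with slide as a random block on the site means and among probes well above background on every array, 3 after median scaling and 8 with the authors' table. It was 516 with no filter on dim probes, 1948 for 32 arrays with the site as a random block, 4601 for 32 arrays as replicates and 89 between Katzenlochbach and KoIc alone. A fit without Katzenlochbach 2 and 4 was also run after seeing the data and is not reported, because those samples had been picked by their measured expression.

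Leaving out 1 array at a time gave 9123 to 9830 probes over 10 sites and 4663 to 5729 over Ko sites. It gave 2146 to 5426 for Wolfsburg and Reitlingstal, 11 to 57 for Vennerbach and Klufterbach, 48 to 128 for Hittelbach and Annabergerbach, 0 to 1 for KoE and KoV2, and 14 to 208 for KoIc and Katzenlochbach. Leaving out 1 site gave 0 to 1808 for brook-named against code-only sites and 2994 to 5381 for Wolfsburg and Reitlingstal against Ko. The share of variance between sites, which holds slide as well, was then 37.9% to 50.1%, lowest without Reitlingstal. For single named contigs, 292 of 347 values under other settings kept direction and side of the threshold, 54 lost the threshold, 1 gained it and 0 reversed. With 1 array or site left out these numbers were 947 of 1032, 82, 3 and 0.

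Title numbers did not pair samples: deviations of same-numbered samples correlated at a median of -0.0171, against 0.00384 for other numbers. With the title number as a replicate block, 14 probes were called for Vennerbach and Klufterbach and 15 for KoIc and Katzenlochbach, and 9265 over 10 sites. Slide as a random block could not be fitted in the F-tests, because each site lies on 1 slide, and tests of gene lists were not run, because the probes have no gene names. Normexp correction ended calls of contigs not well above background in one group, such as comp95105_c0_seq1 and comp285182_c0_seq1, but also those of comp107326_c0_seq2 and comp388159_c0_seq5, well above background on all 32 Ko arrays, whose differences were 1.19 and 1.14 with it, against 1.19 for both without. Contigs comp107326_c0_seq2 and comp388159_c0_seq5 count as 1 measurement, called near the threshold (limma, adjusted p = 0.0486). Of the 26 brook-named calls, only 3 were of probes well above background on every Ko array, and 6 were on no brook-named array. With normexp correction 0 probes were called. The loss therefore also reached brighter probes, but these were too few to tell whether it depended on how dim a probe was.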

Other observations

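The tests of spread within brook-named sites, by the score, by the second set and over all tested probes, and the refits of the covariate test with 1 site left out, were chosen after the results were seen. A second set of 21 probes, both probes of contig comp127391_c0_seq1 among them, varied together within sites. It was found among 207 probes whose range within some site was at least 5 on the log2 scale. The probes of this set are meant below. The mean of the second set lay between -1.70 and 1.11 in code-only samples and between -5.41 and 1.11 in brook-named samples. Klufterbach 3, Hittelbach 4 and Vennerbach 1 were lowest, at -5.41, -4.40 and -3.99, while Klufterbach 5, Hittelbach 6 and Vennerbach 4 lay at 0.11, -0.05 and -0.36. Katzenlochbach 2 and 4 lay at 1.04 and 1.11, and Katzenlochbach 1 and 3 at -2.85 and -1.95. At Vennerbach, Klufterbach, Hittelbach, KoIc and Katzenlochbach, the sample lowest in the second set also had its site's smallest share of spots well above background. At Annabergerbach, KoE and KoV2 it did not. Whether the second set follows array signal rather than the individual was not tested. A further set of 17 contigs was low on Wolfsburg 2, Reitlingstal 1 and Reitlingstal 6, at -2.43 to -1.40, against 2.62 to 3.32 on Ko arrays. The other Wolfsburg and Reitlingstal arrays lay at 1.9 to 3.39. Of these contigs, 16 were called between Wolfsburg and Reitlingstal and the Ko sites. The mean difference of this further set therefore rests mostly on those low-signal arrays.

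One hypothesis was that the brook-named difference follows an individual state tracked by the second set. With the mean of these 21 probes as a covariate and the site as a random block, 1059 probes outside the set were called, against 1948 without the covariate. The count with the covariate was 54.4% of that without, with 1011 probes in both, and 35.6% to 66.0% with 1 site left out, which lies on both sides of the limit of 50% set beforehand. The median absolute log2 difference of the probes called without it was 0.65 before and 0.52 after, so a part played by the state stays open. The other hypothesis, that brook-named sites vary more within a site, stays open. The score's mean within-site SD was 0.351 at brook-named and 0.332 at code-only sites (one-sided exact permutation p = 0.429 over 56 splits of the sites). The median within-site SD over all tested probes was 0.24 to 0.30 at brook-named and 0.15 to 0.25 at code-only sites (same permutation test, p = 0.0536). For the mean of the second set the SDs were 1.73 to 2.26 and 0.10 to 1.19 (same permutation test, p = 0.0179, the smallest possible), but its probes had been picked for their range within sites.

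Splits of the samples argue against chance as the source of the count over 10 sites. There 1 of 100 splits, the real one, gave as many as 9593 and the highest other gave 687. The same holds for the Ko sites (1 of 100, 5386 against 9). Each site lies on 1 slide, so these counts hold site and slide together, and the splits do not tell these apart. For brook-named against code-only sites, 2 of 56 splits gave at least 26 probes, and the highest other gave 134. That split set Vennerbach, Klufterbach and Hittelbach against the rest, and a split with KoV2, KoIc and Katzenlochbach together gave 22. The smaller side of each, and that of the real split with KoE and KoV2, holds both sites of 1 slide. Other splits with such a pair gave 0 or 1, so sharing a slide is not enough to raise the count. Splits without such a pair also gave only 0 or 1, and the real split gave 0 with slide as a random block. A part played by the slide therefore stays open. Between Wolfsburg and Reitlingstal, 4 of 35 splits gave at least 3725 and the highest other gave 6244, so chance could not be excluded, and the 8 samples have a structure other than site. Without the 3 arrays of low signal 2417 probes were called, and at the 3725 probes the median row difference on the other slides was -8.67% of that on slide 1, which argues against a row effect common to all slides but not against one of slide 1 alone. For Vennerbach and Klufterbach 1 of 35 splits, the real one, gave as many as 44, but another gave 42, and the count was 2 with the slide's arrays alone, so the margin over chance was narrow. The splits argue against chance for Hittelbach and Annabergerbach (1 of 35, 96 against 2) and for KoIc and Katzenlochbach (1 of 35, 89 against 1). For a slide pair, 1 of 35 is the smallest share possible, and no adjustment was made for the number of pairs. For KoE and KoV2 all 35 splits gave at least the 0 seen, and the highest other gave 1.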
